A study of Homo sapiens with 11 samples.

How the data were processed

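The series holds 11 RNA sequencing libraries of the small cell lung cancer lines H524 and H209, each with a lentiviral, doxycycline-inducible peptide, M/M-WT or M/M-51. Per the labels' protocols, cells were grown with 1 µg/mL doxycycline for 48 hours, and libraries were made from mRNA selected with oligo-dT out of 500 ng of total RNA. What the peptide names stand for was not taken beyond the labels. Groups were taken from the sample descriptions, and replicate numbers follow the order of deposition, only name libraries and pair none.

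Per the submitters' processing notes, the authors used FastQC 0.11.8, Trimmomatic 0.39, STAR 2.5 and RSEM 1.3.1, and the notes name the human build hg19. Per the file headers, the authors deposited for each library a table of genes with RSEM expected counts, TPM and FPKM, together with gene length and effective length. The expected counts are estimates, since RSEM divides a read that maps to several genes between them, so they need not be whole. The deposited TPM and FPKM values are the same estimates scaled by length and depth by the authors, and were not tested. The tables per isoform were not used here.

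All 55416 gene IDs begin with ENSMUSG, the prefix of mouse genes in Ensembl, which stands against the human label and the human build of the notes. The names of the deposited tables also hold a mouse annotation tag, so the counts were made under a mouse annotation. Which sequence the reads were aligned to was not settled from the sources used here, so every value is a count under the ID in the file. If reads of human cells were counted on mouse gene models, less conserved transcripts would be counted less well. Total counts could then fall short of the reads sequenced. The human gene tables at hand matched 0 of the IDs, and the files do not pair IDs with names. The 24 gene lists fixed beforehand and the named genes chosen by symbol could therefore not be looked up, and the gene list tests with their alternatives were not run. By the rule for named genes, an ID had to have an adjusted p below 0.05, a mean of at least 5 CPM and every M/M-51 library of the line beyond every M/M-WT library, and IDs were ranked by the size of the log2 fold change. The rule as fixed would have counted IDs without a gene name and not printed them. In a departure from it, the first ranked ID per direction and line is printed, 1 each, so that identifiers without names are kept few. IDs from the comparison over both lines and from the test between lines were counted only.

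Total expected counts per library were 492937 to 628996 in the 8 libraries numbered in the 90s and 1600816 to 1687221 in the 3 numbered in the 70s. The mean read length implied by length minus effective length was 79.99 in the 90s set and 79.44 to 79.45 in the 70s set. The share of all counts under the 10 most counted IDs was 14.5% to 15.9% in H524 and 16.4% to 19.1% in H209.

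Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. IDs with low counts were removed with filterByExpr (minimum count 10, by the 4 groups), libraries were scaled by TMM, and a quasi-likelihood model with the 4 groups and an additive library set term was fitted to all 11 libraries, which share 1 estimate of the spread. Contrasts gave M/M-51 against M/M-WT in each line, their mean, their difference, and H524 against H209 with M/M-WT. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05 and no threshold on fold. CPM values are scaled by TMM, and log2 CPM uses a prior count of 2. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Replicates were compared by a chi-square over IDs with a summed count of at least 20. A fold against a group with no count was computed against a floor of 3 counts over the group, and ratios with 1 to 3 counts have 95% exact binomial intervals. An ID was called whole where its expected count lay within 0.005 of a whole number in every library. Of the 4895 tested IDs, 920 (18.8%) were not whole, and IDs that were not whole held 38.6% to 44.5% of a library's counts.

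The tests were tried on simulated data with 200 changed genes among 4895. Counts were drawn from the fitted model itself, with a spread set by abundance alone and no reads shared between IDs. The share of false calls and the share of changed genes recovered therefore need not hold for the real data. For H524, 50 of 100 genes changed by 1.5-fold and 72 of 100 changed by 2-fold were recovered, with 6 false calls among 128. For H209, 26 of 100 and 63 of 100 were recovered, with 2 false calls among 91.

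The design, alternatives and rule for named genes, from which printing IDs without names departs, were fixed before the data were examined. The other settings fixed then were no set term, a set term per line, leaving out the 70s set, each line fitted alone, RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom (limma 3.58.1), other filters and leaving out each library. Where libraries were left out, the 4895 tested IDs were held fixed, a choice made after seeing the data, except those with no count in the libraries left (4893 were tested without the 70s set). Applying the filter anew also changes which IDs are tested. With the filter applied anew and the 70s set left out, 4735 IDs were tested, with 26 higher and 27 lower in H524, 65 and 139 in H209, and 78 and 131 over both lines. A further filter, thinning of the 70s set and a restriction to whole IDs were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.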

Results

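Messenger RNA was sequenced from 2 human small cell lung cancer lines, H524 and H209, that carried a lentiviral construct for one of 2 doxycycline-inducible peptides, M/M-WT or M/M-51. The series describes the treatment as blockade of the KIX domain, a protein-binding domain of the transcriptional co-activators CREBBP and EP300, and its stated comparison is M/M-WT against M/M-51. All cells had received 1 µg/mL doxycycline for 48 hours. No library lacked a peptide, so every change given here is of M/M-51 relative to M/M-WT, not relative to cells without a peptide. There were 3 libraries of H524 with M/M-WT, 3 of H524 with M/M-51, 2 of H209 with M/M-WT and 3 of H209 with M/M-51. The labels do not say that libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

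The library numbers in the sample titles fell into 2 ranges, which are called the 70s set and the 90s set here. The 3 libraries of the 70s set (replicate 1 of H524 M/M-WT, of H524 M/M-51 and of H209 M/M-51) held 1600816 to 1687221 counts. The 8 libraries of the 90s set held 492937 to 628996 counts, a depth at which 3 counts, the limit that a count of 0 allows, correspond to 4.77 to 6.09 CPM, the count scaled to library size, in 1 library. Such limits and all counting intervals cover counting error only. The first principal component of log2 CPM, with 79.5% of the variance, separated the lines, and the second, with 4.10%, separated the sets. The correlation across genes of log2 CPM was 0.948 to 0.981 between libraries of 1 line and 0.693 to 0.727 between libraries of different lines. Replicates of the same set differed by 1.41 to 1.52 times the chi-square expected from sampling noise, and replicates of different sets by 3.61 to 6.28 times. No pair of replicates agreed within sampling noise, so none was merged, which does not show that they came from separate cultures.

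The values came under 55416 gene IDs with the prefix ENSMUSG, which Ensembl gives to mouse genes, although the samples were labelled human. The files do not pair these IDs with gene names, so changes were counted by ID, and only the ID with the largest change in each direction and line is given. At least 1 count was found for 9951 IDs, and 4895 passed the filter on low counts and were tested.

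In H524, 235 of the 4895 IDs differed between the peptides at an adjusted p below 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 129 were higher with M/M-51, by a median log2 fold change of 0.40, and 106 were lower, by a median of -0.64. The medians were the same with the 1 ID that had no count in any M/M-WT library set at its lower bound. Most changes were small, and 23 of the 235 IDs, 5 higher and 18 lower, changed by more than 2-fold. Over all 4895 tested IDs, called or not, the 3 M/M-51 libraries did not overlap the 3 M/M-WT libraries for 1028 IDs, or 21.0%. Chance gives 10% if the library sets, which differed, are ignored.

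The ID with the largest decrease in H524 was ENSMUSG00000026185.9, at 11.8 ± 6.58 CPM with M/M-WT and 0.758 ± 0.828 CPM with M/M-51 (SD, n = 3 each). Its fitted log2 fold change was -3.49 ± 0.63 (SE, edgeR adjusted p = 0.00432). It rested on 27 counts in M/M-WT and 2 in M/M-51, a ratio of 13.6 with a 95% exact binomial counting interval of 3.42 to 118. Without replicate 1 of H524 M/M-51 the log2 fold change was -3.50 and the edgeR adjusted p was 0.0656. ENSMUSG00000026185.9 was far more abundant in H209, at 220 ± 19.6 CPM with M/M-WT (n = 2) and 282 ± 43.1 CPM with M/M-51 (n = 3). The ID with the largest increase in H524 was ENSMUSG00000071516.3, which had no count in the 3 M/M-WT libraries and 43.6 ± 28.5 CPM in the 3 M/M-51 libraries. With 3 counts over the M/M-WT group as the floor, the assigned counts of ENSMUSG00000071516.3 were at least 27.9-fold higher with M/M-51 (edgeR adjusted p = 0.0122). The bound was 23.7-fold in the 90s set and 5.47-fold in the 70s pair, where the M/M-51 library held 10.7 CPM against 57.5 and 62.5 CPM in the 90s set. It was 12.1-fold without replicate 1 of H524 M/M-WT and 54.9-fold without replicate 1 of H524 M/M-51. The counts of ENSMUSG00000071516.3 were not whole numbers, which marks an ID that shares reads with others. The bounds take counts as assigned and do not cover how shared reads were divided. ENSMUSG00000071516.3 varied in H209 from 0 to 28.1 CPM between the 2 M/M-WT libraries. Its edgeR adjusted p was 0.0811 without the library set term in the model and 0.0506 without replicate 1 of H524 M/M-WT.

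The number of calls in H524 depended on the handling of the library sets and on which libraries were kept. Leaving out the 70s set also removes the deepest library of each H524 group. An effect of the sets on that count cannot be told apart from fewer libraries and less depth. Within the 90s set alone, with 2 libraries per group, 49 IDs passed, 23 higher and 26 lower, and 42 of them were among the 235. The 70s set holds 1 H524 library per peptide and gives no test by itself. In that pair, 44 of the 49 IDs differed in the same direction as in the 90s set, against 64.4% of all tested IDs. Without the set term 59 IDs passed, with DESeq2 125 and among IDs with whole counts 365, and leaving out any 1 of the 6 H524 libraries gave between 51 and 144.

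In H209, 205 of the 4895 IDs differed between the peptides by the same test, 76 higher with M/M-51 by a median log2 fold change of 0.50 and 129 lower by a median of -0.64. The medians did not move with the 3 IDs that had no count in one of the groups set at their bounds. More than 2-fold changes were found for 45 IDs, 16 higher and 29 lower. Over all 4895 tested IDs, the groups did not overlap for 1645, or 33.6%. With 2 libraries against 3, chance gives 20% if the library sets are ignored. Within the 90s set, with 2 libraries per group, 201 IDs passed, 65 higher and 136 lower, and 157 of them were among the 205. The M/M-WT group of H209 has no library in the 70s set. The count was 113 without the set term, 130 with DESeq2 and 325 with no filter on low counts, and leaving out 1 of the H209 libraries of the 90s set gave between 89 and 127.

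The ID with the largest increase in H209 was ENSMUSG00000009927.10, with no count in either M/M-WT library and 653 ± 63.5 CPM in the 3 M/M-51 libraries. Its assigned counts were at least 256-fold higher, with 3 counts over the M/M-WT group as the floor (edgeR adjusted p = 1.91e-08). This bound covers counting error only, not how reads shared with other IDs were divided. With only 1 M/M-WT library in the floor, the bound was 134-fold without M/M-WT replicate 1 and 123-fold without M/M-WT replicate 2. No count was assigned to ENSMUSG00000009927.10 in the 6 H524 libraries. The ID with the largest decrease was ENSMUSG00000067344.8, at 670 ± 57.7 CPM with M/M-WT (n = 2) and 42.0 ± 36.6 CPM with M/M-51 (n = 3), a log2 fold change of -3.90 ± 0.33 (SE, edgeR adjusted p = 1.2e-06). In H524 it stood at 1030 ± 50.8 CPM with M/M-WT and 1056 ± 40.8 CPM with M/M-51 (n = 3 each). Neither ID had whole counts in every library. In H209, both had whole counts in the 2 M/M-WT libraries and in M/M-51 replicate 3. In that replicate 418 counts were assigned to ENSMUSG00000009927.10 and 0 to ENSMUSG00000067344.8. The sum of ENSMUSG00000009927.10 and ENSMUSG00000067344.8 in H209 was 670 ± 57.7 CPM with M/M-WT and 695 ± 34.6 CPM with M/M-51. Their summed counts differed between the peptides by a log2 fold change of 0.05 ± 0.08 (SE, edgeR adjusted p = 0.817), so the pair together did not show the change that each ID showed alone.

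**Figure D1:**
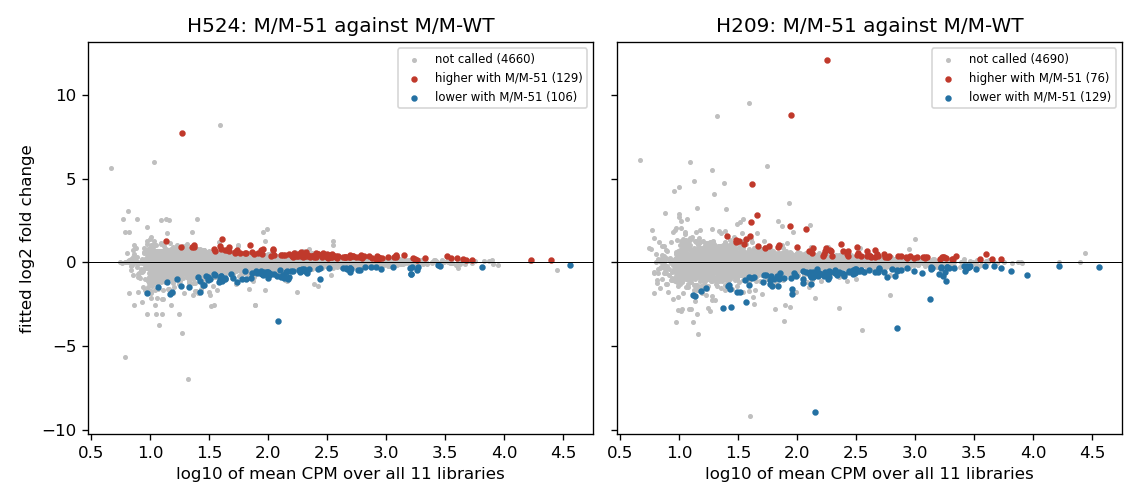
Fitted log2 fold change of M/M-51 against M/M-WT for each of the 4895 tested IDs (points) against the log10 of its mean CPM over the 11 libraries, in H524 (left) and H209 (right). Coloured points are the 235 IDs called in H524 and the 205 called in H209 at an adjusted p below 0.05. Fitted values of IDs with no count in one group depend on a prior count.

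**Figure D2:**
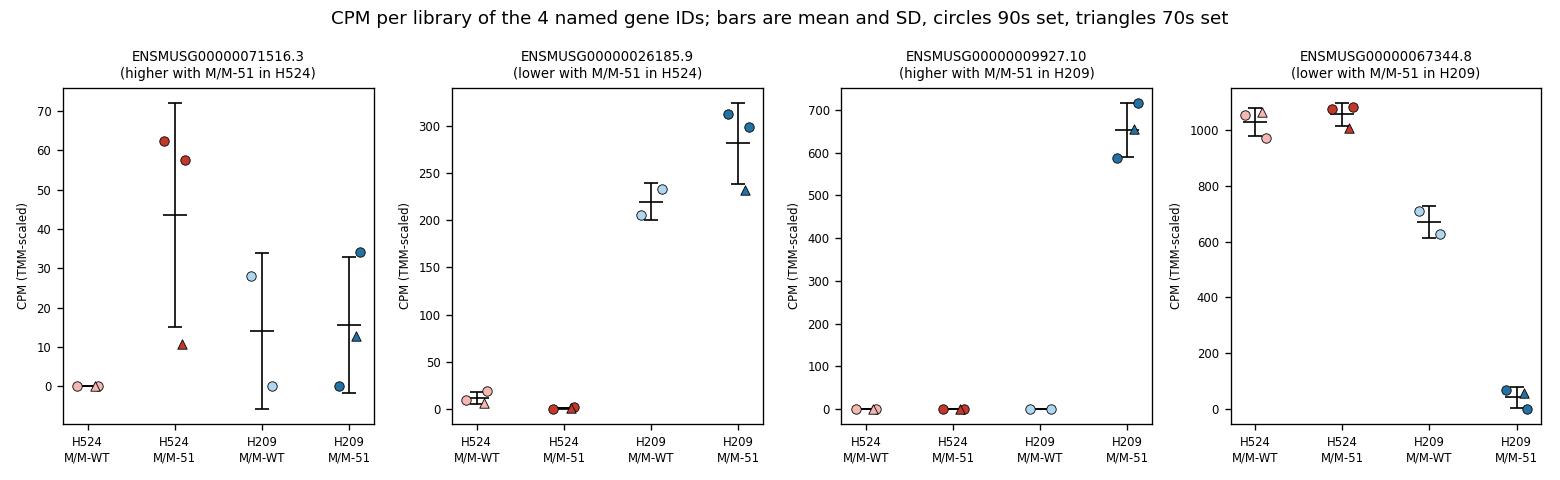
CPM per library of the 4 named IDs by line and peptide, with circles for the 90s set, triangles for the 70s set, and bars for the mean and SD of each group. In H209, ENSMUSG00000009927.10 stood at 0 in both M/M-WT libraries and ENSMUSG00000067344.8 fell from a mean of 670 to 42.0 CPM.

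Over both lines, with equal weight for each, 374 IDs differed between the peptides, 168 higher and 206 lower with M/M-51. Their median log2 fold changes were 0.30 and -0.47. In the 90s set alone 204 IDs passed, of which 181 were among the 374, and the count was 201 without the set term and 218 with DESeq2. Leaving out 1 library gave between 207 and 340. The same IDs were called in H524 and in H209 more often than independent lists would share. Among 46 IDs called in both lines, 18 were higher in both, where independent lists share 2 (one-sided Fisher's exact test, p = 3.94e-13). A further 24 were lower in both, where independent lists share 2.79 (Fisher's exact test, p = 9.4e-17), and 4 changed in opposite directions. Both lists came from the same fit and share its set term, and IDs are not independent, so these p-values only describe the overlap. Across all 4895 IDs, which are not independent replicates, the log2 fold changes of the lines correlated weakly, with Pearson's r = 0.138 and Spearman's rho = 0.197. Within the 90s set r was 0.148.

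**Figure D3:**
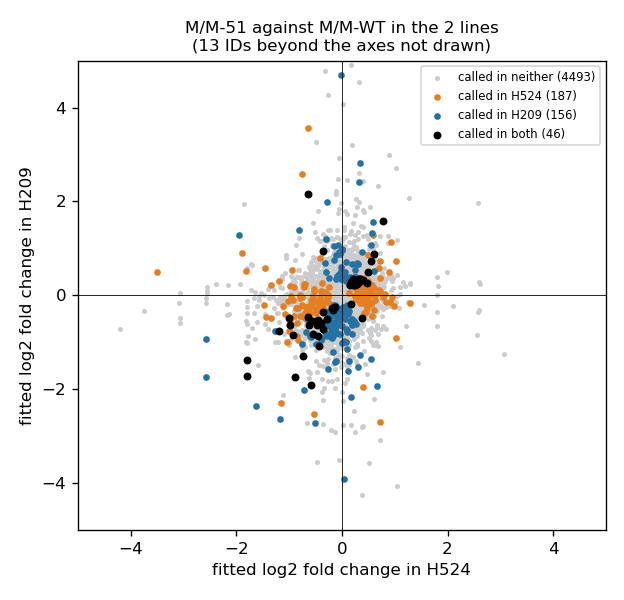
Fitted log2 fold change of M/M-51 against M/M-WT in H209 against that in H524, with 1 point per tested ID and 13 IDs beyond the axis limit of 5 not drawn. Black points are the 46 IDs called in both lines, of which 42 changed in the same direction.

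The effect of M/M-51 against M/M-WT differed between the lines for 55 IDs by a test of the difference itself (edgeR, adjusted p below 0.05). The fitted change was larger in H209 for 47 of them and larger in H524 for 8, and 46 had opposite signs in the lines. Picking IDs for a difference favours opposite signs, so this count does not show that the lines responded in opposite directions. Of the 55, 39 were called in H209 alone, 7 in H524 alone, 6 in both and 3 in neither. ENSMUSG00000026185.9 was among them, with a log2 effect in H524 minus that in H209 of -3.99 (adjusted p = 0.00275). ENSMUSG00000067344.8 was also among them, with a difference of 3.94 (adjusted p = 7.44e-05). For its counts summed with those of ENSMUSG00000009927.10, the difference between the lines was only -0.022 (edgeR adjusted p = 0.996). The counts of 22 of the 55 IDs were not whole. The count was 23 without the library set term, 33 with the 70s set thinned, 88 among IDs with whole counts and 147 with no filter on low counts, and leaving out 1 library gave between 21 and 53.

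The lines themselves differed far more than the peptides. With M/M-WT, 2765 of the 4895 IDs, or 56.5%, differed between H524 and H209, 1365 higher in H524 by a median log2 fold change of 1.11 and 1400 lower by a median of -1.17. More than 2-fold differences were found for 1592 IDs.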

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

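The test of the summed counts of an ID pair, the odds ratios for counts that were not whole and the correlation among whole IDs were chosen after the results they concern were seen. Outlying libraries were not tested in groups of 2 and 3.

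The effect of M/M-51 against M/M-WT differed between H524 and H209 for 55 IDs by the interaction test. For ENSMUSG00000026185.9 the log2 effect in H524 minus that in H209 was -3.99, and for ENSMUSG00000067344.8 it was 3.94. For the summed counts of ENSMUSG00000067344.8 and ENSMUSG00000009927.10 it was -0.022 (edgeR adjusted p = 0.996).

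The opposite changes of ENSMUSG00000009927.10 and ENSMUSG00000067344.8 in H209 were weighed first. If reads were divided differently between near-identical copies, the sum of the pair would stay level, and the summed log2 fold change in H209 was 0.054 ± 0.081 (SE, edgeR adjusted p = 0.817). The pair was chosen as the largest change in each direction, which does not fix the size of the fall and the rise in CPM. The value is consistent with a shift of shared reads between the IDs rather than a change in their total, while a difference in sequence between the H209 cell populations, which could also move reads, and a biological switch were not tested. Over all 45 IDs that changed more than 2-fold in H209, counts were more often not whole than among other IDs, with an odds ratio of 2.65 (95% interval 1.36 to 5.04, Fisher's exact test, p = 0.00309) and of 3.19 within 10 groups of like abundance (1.60 to 6.18). The 23 IDs that changed more than 2-fold in H524 did not show this clearly, with odds ratios of 1.53 (0.492 to 4.08, Fisher's exact test, p = 0.419) and, within groups of like abundance, 2.18 (0.696 to 5.88). Of all calls, 24.3% in H524 (p = 0.0322) and 35.1% in H209 (p = 1.45e-08) were not whole, against 18.8% of all tested IDs (Fisher's exact tests against the IDs not called), and within groups of like abundance the odds ratios were 0.861 (0.611 to 1.20) and 1.42 (1.02 to 1.97).

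The library sets differed for 302 IDs, 203 higher in the 70s set and 99 lower. A greater number of counts alone was argued against by thinning the 70s set to the mean depth of the 90s set, after which 192 of the 302 IDs were still called. The thinned counts keep the division of shared reads made at full depth, so an effect of depth on that division was not tested. Gene length was argued against by a Spearman's rho across IDs of -0.066 between length and the set difference. Shared reads remain a candidate explanation for part of it, since 54.0% of the IDs called between the sets had counts that were not whole, against 16.5% of the rest, with an odds ratio of 4.66 within 10 groups of like abundance (3.60 to 6.03). The read length implied by the files also differed between the sets, and whether that or another step of library making moved the reads was not tested, nor was a biological explanation, since the labels give none.

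The low correlation of the fold changes between the lines, 0.138, was set against counting noise. With noise as the whole reason, r was predicted to reach at least 0.4 among the 1224 IDs with the most counts, and it was 0.116 there, with a rho of 0.31. The 1224 include ENSMUSG00000009927.10, whose fitted log2 fold change of 12.11 in H209 depends on a prior count and can weigh heavily on r. Among the 822 of them with whole counts, which leave that ID out, r was 0.24, also below 0.4. The 1224 IDs still carry counting noise, and the r that noise alone would leave among them was not computed. Spearman's rho was 0.197 over all tested IDs and 0.31 among the 1224. The test therefore cannot decide whether noise accounts for part or all of the low value, and shared reads may also contribute. That the lines respond differently stays open.

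Other splits of the libraries were fitted for comparison. Of the 10 splits of the 6 H524 libraries, 1, the real one, gave as many as 235 IDs, and the highest of the others gave 1 ID, but 10 splits are too few for a share under 0.05. Of 100 splits within the lines, the real one included, 1 gave as many as 374 IDs for both lines, and the highest of the others gave 30. A random choice among these splits would thus rarely give a count of that size. If libraries of a group came from 1 culture, the real split could stand out whatever the peptide did. The splits therefore do not show an effect of the peptide.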

How the results depend on the processing

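The restriction to whole IDs, the filter of 50 CPM in 5 libraries, the thinning of the 70s set, the correlations without the 70s set or among whole IDs, and the holding of the tested IDs where libraries were left out were chosen after seeing the data. The cause was not tested unless given. The count in H524 (235) was 59 without the set term, 49 without the 70s set (fewer samples), 125 with DESeq2 and 365 among whole IDs. That in H209 (205) was 113 without the set term, 130 with DESeq2 and 325 with no filter, where 9951 IDs were tested. The count over both lines (374) was 201 without the set term, 204 without the 70s set and 218 with DESeq2. The difference between the lines (55) was 23 without the set term, 147 with no filter, 88 among whole IDs and 33 with the 70s set thinned. Settings not listed for a count kept it within 1.5 times, and so did the 3 settings of the line comparison (2223 to 2768).

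Leaving out 1 library gave 51 to 259 IDs in H524, 89 to 205 in H209, 207 to 340 over both lines and 21 to 53 for the difference between the lines. In H524, the count was 73, 120 and 144 without M/M-WT replicates 1, 2 and 3, and 51, 132 and 136 without M/M-51 replicates 1, 2 and 3. In H209, it was 127 and 89 without M/M-WT replicates 1 and 2, and 114 and 120 without M/M-51 replicates 2 and 3. Over both lines it was 207 without H524 M/M-WT replicate 1, and 247 and 234 without H209 M/M-WT replicates 1 and 2. The difference between the lines was called for 31 IDs without H524 M/M-WT replicate 2, 21 and 36 without H524 M/M-51 replicates 1 and 3, 31 without H209 M/M-WT replicate 2, and 35 and 34 without H209 M/M-51 replicates 2 and 3. With 1 H209 M/M-WT library left, that library is assumed to vary like the other groups.

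Of 96 combinations of the 4 named IDs with 24 settings, 87 gave a value, all in the same direction, and 84 passed. In 8 the ID was not among those tested (for ENSMUSG00000071516.3 and ENSMUSG00000026185.9 with each line fitted alone, the rest under a filter or among whole IDs), and DESeq2 gave no adjusted p for ENSMUSG00000071516.3. Those that did not pass were ENSMUSG00000071516.3 without the set term (adjusted p = 0.0811, its highest) and without H524 M/M-WT replicate 1 (adjusted p = 0.0506), and ENSMUSG00000026185.9 without H524 M/M-51 replicate 1 (adjusted p = 0.0656, its highest). The filter of 1 CPM in 5 libraries, meant to be stricter, kept 7469 IDs, more than 4895, so that of 50 CPM was added. The gene list tests were not run for lack of names. At this depth and number of libraries, which were not varied apart, 50 of 100 simulated genes changed by 1.5-fold were recovered for H524 and 26 of 100 for H209. These shares need not hold for the real data.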

Other observations

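The following values were chosen after seeing the data. With a mean of at least 50 CPM in the 6 H524 libraries, 25 IDs had a rounded count of 0 in each of the 5 H209 libraries, which allows up to 0.779 CPM over that line, and 23 of the 25 had whole counts. The reverse held for 22 IDs, at least 50 CPM in H209 with a rounded count of 0 in each H524 library, which allows up to 0.531 CPM, and 14 of the 22 had whole counts. Of the 55416 IDs, 45465 had a rounded count of 0 in all 11 libraries.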
